A study of Salmo salar with 6 samples.

How the data were processed

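The samples were 6 pools of head kidney RNA from Atlantic salmon, 3 of fish fed a basal diet and 3 of fish fed that diet with 0.1% MPLE, grouped by the titles in the labels. Per the labels' protocols, Cy3-labelled cRNA was made from total RNA together with spike-in RNA and hybridised to one-colour Agilent arrays. Per the file headers, the arrays were of design 084881, scanned on an Agilent G2505C and read with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, which gives for each spot an intensity that is background-subtracted and detrended within its array and not scaled between arrays. The series values the authors deposited are log2 values: each column equalled log2 of the same array's background-subtracted intensity within 5e-09, left empty where that was 0 or below, with column medians from 5.19 (control pool 3) to 7.52 (MPLE pool 1) and no scaling between arrays. The direction of these values needs no dye orientation, since the arrays have 1 colour. The series design text speaks of a reference design with the control diet as reference, which differs from the one-colour protocols and files, and the files were followed. Pools are separate RNA samples, each on its own array, so p-values measure the spread between pools of fish together with that between arrays and labelling reactions. The labels give differing numbers of tanks and do not say which tanks each pool came from, so tank could not enter the fit, pools of a diet were possibly drawn from shared tanks, and a difference between tanks cannot be told apart from diet.

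The processed intensity was turned to log2, and each array's 75th percentile over the 42438 spots that are not controls was subtracted. Spots flagged as population or non-uniformity outliers (6 to 205 per array) were left out, 0 spots were flagged as saturated, and spots of a probe were averaged. Probes entered where well above background on every array of at least 1 diet, 23130 in all, and a probe with several spots counted as such where any of them was. The fit was limma 3.58.1 (lmFit and eBayes, R 4.3.3) with diet alone as a term, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. A gene was read at its probe with the highest mean signal over all 6 arrays, with the adjusted p of the probe fit. Of 102 genes with more than 1 tested probe, 1 (LOC106606391) had probes pointing both ways at unadjusted p under 0.05.

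Probe names hold RefSeq accessions for 40932 of 42386 probes. Matched without versions to a table of RefSeq genes of assembly Ssal_v3.1, 25641 probes had a gene and 8297 a gene with a name, 142 of these through a synonym. The genome build behind the array's probes is not given in the sources used here, so the table served for names only and no coordinates are given. Names in the text were chosen by a rule fixed before the data were examined: in each direction, the 8 named genes with the largest change among those past the adjusted threshold whose arrays did not overlap between diets, filled up from genes at unadjusted p under 0.05, and for each gene list the 3 members with the smallest p, or 5 for a list past its threshold. Genes outside the rule (rpl38, rpl34, rpl13, agxt2, tpm2, fgg, eno3, fbp2 and the genes with only a locus number) were named after their values were seen. The rule skipped 34 genes past the threshold that had no name.

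The 44 gene lists were fixed before the data were examined and matched by symbol, since the files hold no gene descriptions. Lists with at least 5 genes measured on every array, 37 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry's test asks whether a list's genes move one way on balance, not whether they differ from other genes.

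Alternatives fixed in advance were quantile normalization, median centring, no filter on dim probes, only probes well above background on all 6 arrays, outlier spots kept, the deposited series values, an intensity trend with robust variance, array weights, the pool number as a block, leaving out each array, other thresholds, and the mean of all probes of a gene. The normexp correction planned for mean signals was run on median signals (offset 50), which the files hold. That alternative, centring on spike-in probes, and adjustment over 1 probe per gene were chosen after seeing the data. The spike-in centring subtracted each array's mean log2 signal over all spots of the 10 spike-in probes. These include the 2 that differed between the diets past the adjusted threshold, so it is no independent calibration. Slide was not run as a block because each slide carried 1 array of these samples. Matching by symbol alone was the only matching possible and so is no separate alternative.

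The model was tested on simulated data made from the means and spreads of 22720 probes of the diet comparison. With 100 probes changed by 1 on the log2 scale, 0 passed the adjusted threshold and 78 the unadjusted one. With 100 changed by 2, 25 passed the adjusted and 92 the unadjusted threshold, and 1 unchanged probe was called. Of the 37 lists none was called without a shift. The simulated probes were drawn independently, while the estimated correlation was 0.3 in the ribosomal list and 0.59 in the skeletal muscle list. The simulation therefore does not show how often lists of correlated genes are called without a shift. Both diets were also drawn with the same SD for a probe and without shifts of whole arrays. In the data the median SD of a probe was 0.50 among control pools and 0.21 among MPLE pools. How often unchanged probes are called under such spreads is thus not shown either.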

Results

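Gene expression was measured in the head kidney of Atlantic salmon, the organ in which fish make blood cells, hold lymphoid tissue and secrete cortisol and catecholamines. The fish had eaten for 133 days either a basal diet (control, 0% inclusion) or that diet with 0.1% of a phytogenic additive from sage and lemon verbena, named MPLE in the labels and described there as rich in ursolic acid and other triterpenes. RNA was pooled from 6 fish at a time, and 3 pools per diet were each hybridised to 1 one-colour array. The arrays carried 42386 probes for transcripts. Between 18046 spots (control pool 3) and 33020 spots (MPLE pool 2) of the 42438 were well above background. The 75th percentile of the processed signal was 394, 470 and 138 intensity units in control pools 1, 2 and 3. It was 710, 499 and 570 in MPLE pools 1, 2 and 3, so every MPLE array was brighter than every control array by this measure. The number of arrays limits the precision. Signals are given as log2 values relative to each array's 75th percentile, and changes as MPLE minus control.

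The first comparison asked which transcripts differed between the diets. In fish fed MPLE, transcripts of blzf1, a Golgi matrix protein, of lasp1, an actin-binding LIM and SH3 domain protein, of fgd4a, an exchange factor for Cdc42, and of rpl8, a protein of the large ribosomal subunit, rose. Those of agxtb, an alanine-glyoxylate aminotransferase, of sema6bb, a semaphorin, and of rell2, a RELT-like membrane protein, fell. The level of blzf1 was -0.78 ± 0.12 in control pools and 1.59 ± 0.38 in MPLE pools (SD, n = 3 each), a 5.19-fold difference with an adjusted p = 0.0379 from limma. The level of sema6bb was -0.51 ± 0.28 in control pools and -2.97 ± 0.04 in MPLE pools (SD, n = 3 each), a log2 change of -2.46 with an adjusted p = 0.0322.

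The other genes given as higher were those with the highest log2 changes among named genes past the adjusted threshold. Of these, fgd4a rose by 2.60 and rfwd3, a ubiquitin ligase of the DNA damage response, by 2.38. The rise was 2.20 for lasp1, 2.14 for rpl8 and 1.96 for rs3a. All of these had adjusted p between 0.0357 and 0.0472 by limma. The probe of fgd4a was well above background on 2 of the 3 control arrays and that of rfwd3 on 1. The probes of phf1, a Polycomb-associated protein, and catip, a protein linked to cilia formation, were not well above background on any control array. For such probes the difference is a bound, the mean of the brighter diet against the mean, per array, of the higher of the probe's own signal and the lowest signal among spots well above background. By this bound, in the processed intensities, phf1 was at least 4.41-fold higher with MPLE and catip at least 2.77-fold. The adjusted p = 0.0379 and 0.0322 from limma belong to their full differences, not to the bounds. Such bounds, here and below, need not hold under another background correction. Among the genes that fell, agxtb changed by -2.72 (adjusted p = 0.0396) and rell2 by -2.24 (adjusted p = 0.0357). The probe of agxtb was well above background on 2 of the 3 MPLE arrays and that of rell2 on 1. For all of these genes, every MPLE array lay on one side of every control array, which the naming rule required of them. Many more probes did not overlap between diets without passing the adjusted threshold, 2743 of them lower counting those that passed, and the naming rule filled up the lower side with the 5 named genes of the most negative change among those at unadjusted p under 0.05: aanat1, the enzyme that acetylates serotonin, at -3.30 (adjusted p = 0.0619), the flavin monooxygenase fmo5 at -3.16 (adjusted p = 0.0725), muscle creatine kinase ckmb, 7.97-fold lower (adjusted p = 0.135), AMP deaminase ampd1 at -2.66 (adjusted p = 0.11) and the gluconeogenic enzyme pck1 at -2.61 (adjusted p = 0.14). Of these, aanat1, ampd1 and pck1 were well above background on 2 of the 3 MPLE arrays and fmo5 on 1. After normexp background correction, chosen after seeing the data, the log2 changes were 0.42 for phf1, 0.05 for catip, 0.54 for rfwd3 and 1.15 for lasp1. For the other genes past the threshold, the changes smallest in absolute size over all alternatives were 1.54 for fgd4a, 1.93 for blzf1 and 1.69 for rpl8. They were 1.52 for rs3a, -1.88 for agxtb, -1.52 for sema6bb and -1.44 for rell2. All of the named genes that rose or fell lost the call without control pool 1, without any 1 of the MPLE pools, without the filter on dim probes, when adjusted over 1 probe per gene, and in the deposited series values, which gave no result for catip. With spike-in centring, also chosen after seeing the data, agxtb, sema6bb and rell2 passed and none of the named genes that rose did.

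**Figure D1:**
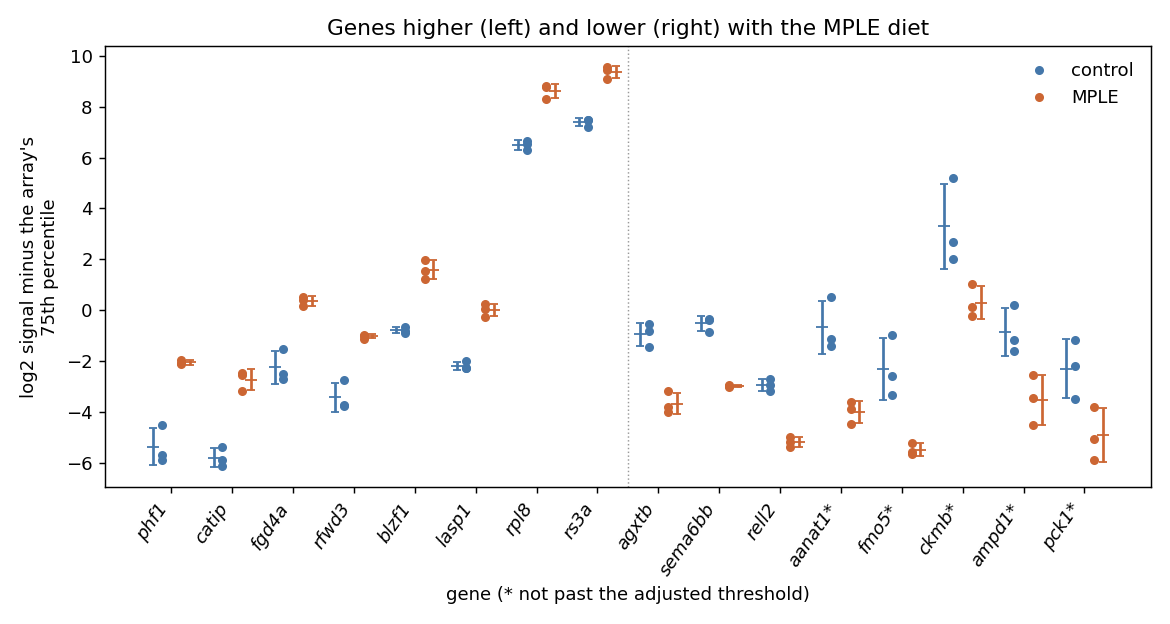
Signal of the named genes on each array, as log2 signal minus the array's 75th percentile; points are the 3 control and 3 MPLE pools, and bars are the mean ± SD of each diet. The naming rule required every MPLE point to lie on one side of every control point, as for blzf1 (-0.78 ± 0.12 in control, 1.59 ± 0.38 with MPLE), and genes marked * did not pass the adjusted threshold.

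Over all 23130 probes tested, 108 passed the adjusted threshold of 0.05, 97 higher and 11 lower with MPLE. Their absolute log2 changes ran from 1.71 to 5.65. Of these 108 probes, 37 were well above background on all 6 arrays, as were 16868 of the 23130 tested. The others called were near background on at least 1 array, and 25 were not well above background on any control array. No gene of the reference table matched 60 of the 108. At 1 probe per gene, 47 of 15507 genes passed, 42 higher and 5 lower, and 13 of the 47 had a gene name. The 5 lower genes were agxtb, sema6bb, rell2 and the unnamed LOC106579933 (-2.34) and LOC106568176 (-1.71). At an unadjusted p under 0.05, 4024 probes differed, 2661 higher and 1363 lower, against 1156 for 5% of the probes tested. The 3 arrays of one diet did not overlap the 3 of the other for 28.2% of probes. Chance gives 10% for probes with a value on every array that were not filtered by diet. The filter on dim probes used the diets, so the share by chance among the probes tested may be higher and was not computed. The split between higher and lower depended on the scaling and background correction. At unadjusted p it was 1579 higher and 2461 lower after normexp correction, 2238 and 450 in the deposited series values, and 929 and 7313 when arrays were centred on the spike-in probes. The mean used for that centring holds E1A_r60_3 and E1A_r60_n9, which were 2.91 and 2.15 higher on MPLE arrays. It moved probes with a value on every array by -0.44. Among probes well above background on all 6 arrays, 1472 were higher and 1443 lower at unadjusted p, and 90 higher and 22 lower at adjusted p. Of these 112 past the adjusted threshold, 37 were among the 108. At adjusted p, that spike-in centring gave 8 higher and 6 lower probes, and the deposited series values 9 and 0.

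Adjusting over the 15507 genes alone, at 1 probe per gene, left 1 gene, LOC106612733 (log2 change 3.84, adjusted p = 0.0132), named after its value was seen. By limma, no probe passed without MPLE pool 1, 2 or 3 (2730, 2503 and 2095 probes at unadjusted p), 5 passed without control pool 1, 164 without control pool 2 and 140 without control pool 3.

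The arrays of the 2 diets also differed in RNA that was not from the fish. Per the labels' protocols a kit of spike-in RNA was added to each labelling reaction. Of its 10 probes, each with 32 spots per array, E1A_r60_3 was at -4.68 ± 0.35 on control arrays and -1.77 ± 0.23 on MPLE arrays (SD, n = 3 each), a difference of 2.91 (adjusted p = 0.000154 over the 10 probes). On the control arrays 1 to 9 of its 32 spots were well above background, and against the lowest signal of spots well above background the difference was at least 2.42. The probe E1A_r60_n9, with all spots well above background on every array, was at 6.36 ± 0.68 and 8.51 ± 0.07 (SD, n = 3 each), a difference of 2.15 (adjusted p = 0.00287). Of the other 8, E1A_r60_a104 had 0 spots well above background on the control arrays, the rest differed by -0.39 to 0.71, and none passed. Of other control probes, with 2 spots each, DCP_1_4 differed by 1.04 (adjusted p = 0.0472 over those probes). Each of the 6 arrays lay on its own slide, 0 slides held both diets, no position on a slide held both diets, and the control arrays were scanned before the MPLE arrays, so slide, position, scan order and diet cannot be told apart.

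**Figure D2:**
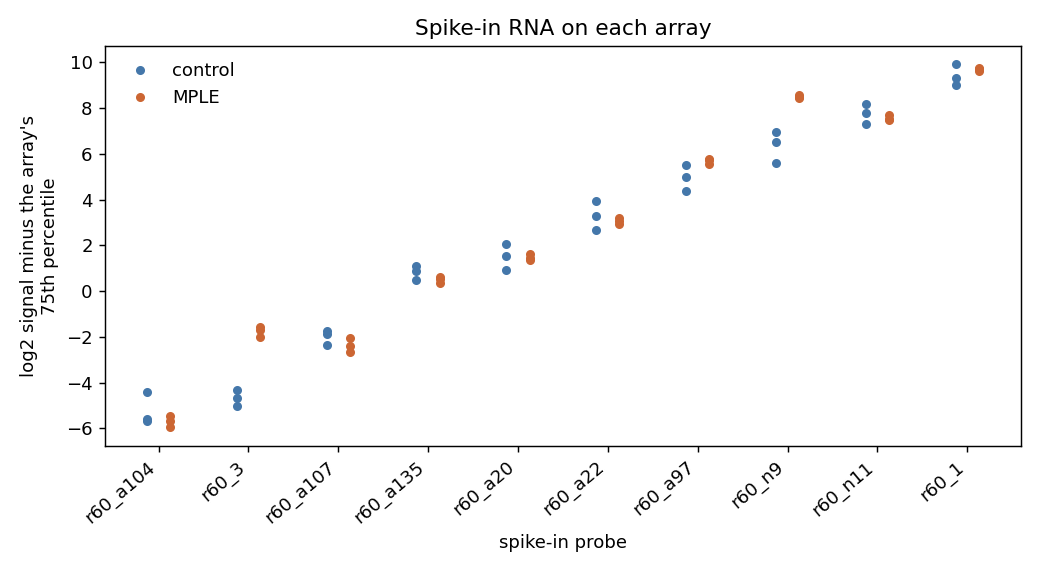
Signal of the 10 spike-in probes on each array, as log2 signal minus the array's 75th percentile, with a point per pool and diet. The points of r60_3, near background on control arrays, and of r60_n9 are 2.91 and 2.15 higher on average on MPLE arrays, and those of the other probes differ by -0.39 to 0.71, leaving aside r60_a104, which was not well above background on any control array.

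Separation of the arrays was described without a test. The first principal component held 51.5% of the variance of 22720 probes and ran from -140.4 for control pool 3 to 73.5 for MPLE pool 1. All 3 MPLE pools scored above all control pools, of which control pool 2 came nearest with 2.63. Correlations across probes, which are not independent replicates, were 0.959 to 0.984 among MPLE arrays, 0.893 to 0.93 among control arrays and 0.848 to 0.949 between diets. The median SD of a probe was 0.50 among control pools and 0.21 among MPLE pools. Spike-in probes, which hold no fish RNA, also spread on this scale. Their SD on control and MPLE arrays was 0.475 and 0.080 for E1A_r60_1 and 0.443 and 0.103 for E1A_r60_n11. For E1A_r60_a107 it was alike, 0.313 and 0.315. The spread within a diet is thus not that of the fish alone.

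The second comparison asked whether lists of genes fixed from textbook knowledge shifted together. Ribosomal protein genes rose as a list with MPLE, and skeletal muscle genes fell, by camera with a preset correlation. For both lists the adjusted p = 0.957 with an estimated correlation. Of the 38 ribosomal protein genes tested, 36 had a positive log2 change, with a median of 0.72. Among these 38, only rpl8 passed when adjusted over all probes, and 18 were higher adjusted over the list alone. The gene rs3a, which also passed by limma (1.96, adjusted p = 0.0396), was not among the 38, since the list holds the symbol rps3a. The changes of rpl12 (2.62), rps7 (1.93), rpl27 (1.67) and rps16 (1.24) had adjusted p between 0.0619 and 0.078, the first 3 of them from 2 MPLE pools, while rpl38 (0.15), rpl34 (0.03) and rpl13 (-0.26) lay near no difference. The set test used the 21 genes with a value on every array, since outlier flags removed others, and camera gave an adjusted p = 1.37e-06 with a median of 0.74. The adjusted p = 0.957 with an estimated correlation, and 0.216 by fry. The spike-in probe E1A_r60_n9, of similar brightness, was 2.15 higher on the same arrays, while the 2 others as bright, E1A_r60_n11 and E1A_r60_1, differed by -0.18 and 0.29.

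Of the 8 skeletal muscle genes tested, 7 had a negative change, with a median of -1.49 and a camera adjusted p = 0.00115. The adjusted p = 0.957 with an estimated correlation, 0.845 by fry, and 0.149 by camera with spike-in centring, and over all alternatives it ran from 5.12e-07 to 0.957. None passed when adjusted over all probes, and 5 were lower adjusted over the list alone: ckmb (7.97-fold), the calcium store protein casq1b (-2.57), the actinin actn3b (-2.16), the troponin TNNT3 (-1.69) and the calcium pump atp2a1l (-1.29). These 5 were lower on every MPLE array than on every control array. Control pool 3 had the highest level of ckmb, 5.18, against 2.70 and 2.02 in the other control pools and -0.23, 0.12 and 1.02 in the MPLE pools.

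The other 35 lists tested had camera adjusted p from 0.408 to 0.942, and none passed with an estimated correlation or by fry. In 43 of the 44 lists no gene passed when adjusted over all probes, so the values that follow are log2 changes of genes that did not pass. Small medians depended on the processing: leaving aside settings that only recentre the arrays, 28 of the 37 lists changed sign under at least 1 alternative, as monocyte genes did without the filter on dim probes (-0.18) and T cell genes with only probes well above background on all arrays (-0.21). Of the genes named below, ctrl was well above background on 1 of the 3 control arrays, and eomes, pnmt, ccl20a.3, tnfaip3, ikbkb, gss, cyp1a, birc5b, ccne1, bop1 and klf4 on 2, and thrsp, slc22a6l and hpxa on 2 of the 3 MPLE arrays; others are described where they are named. After normexp correction the changes of pik3ca (-0.19), bop1 (-0.18), cyp1a (-0.11), hamp (-0.08), tapbp (-0.05), ccl20a.3 (-0.02), ctrl (-0.70), fli1 (0.22) and ctsh (0.43) had the opposite sign to that given below, as had those of gp9 (0.40), pou2af1 (0.10), tnfrsf13b (0.06), cpb1 (0.55) and pnmt (0.43) in the deposited series values and of mrap (0.42) with array weights. Outlier flags left 2 MPLE pools for hba, hbb, cfd, cd74a and gapdhs and 2 control pools for mpx, hspa8 and pik3r1. In 7 lists the median and the mean differed in sign: regulatory cytokines, antimicrobial proteins, phagosome genes, fatty acid synthesis, xenobiotic metabolism, oxidative phosphorylation and endothelium.

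**Figure D3:**
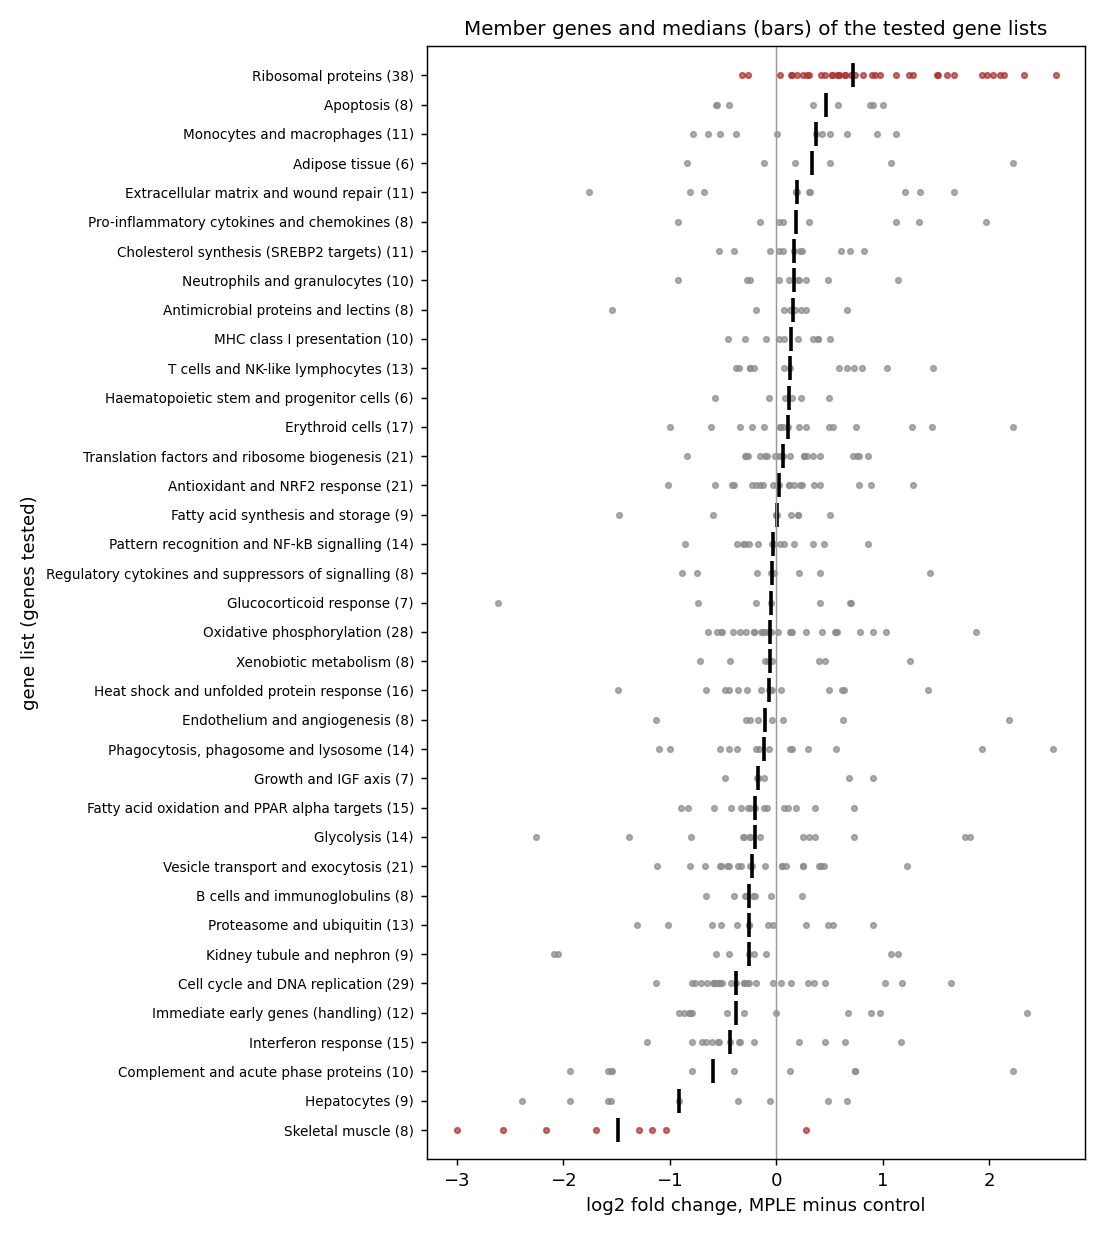
Log2 change (MPLE minus control) of each member of the 37 tested lists, with the median as a bar and the number of genes tested in brackets; lists past the camera threshold are in red. Ribosomal proteins have a median of 0.72 and skeletal muscle genes of -1.49, and the other lists have medians between these.

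Among immune functions, the 15 interferon response genes had a median of -0.44 (adjusted p = 0.524), with irf7 at -1.21, lower adjusted over the list alone, and dhx58 at -0.79, while ifng, not well above background on any control array, had a log2 change of 1.17 (adjusted p = 0.199), a bound of at least 1.96-fold higher, and of -0.34 after normexp correction. Pro-inflammatory cytokines and chemokines had a median of 0.19 over 8 genes, with il6 at 1.34, ccl20a.3 at 1.12 and cxcl12a at -0.93. Of 8 regulatory cytokines and suppressors (median -0.04), tnfaip3, an inhibitor of NF-kB signalling, was higher adjusted over the list alone (1.44), and tgfb1a (-0.89) and il1rap (-0.75) were not past it. Over the alternatives tnfaip3 ran from 0.44 to 2.15. The 14 pattern recognition genes had a median of -0.03, with tlr9 at -0.85, ikbkb at 0.86 and card9 at 0.45. The 8 antimicrobial proteins and lectins had a median of 0.16, with hp at -1.54, hamp at 0.67 and lgals3a at 0.23. Complement and acute phase genes had a median of -0.59 over 10 genes, with complement factor D, cfd, higher adjusted over the list alone (2.22), hp at -1.54 and saa5 at 0.74. The median of the 9 complement and acute phase genes used in the set test, -0.79 (adjusted p = 0.762), ran from -2.17 to -0.02 over the alternatives, with adjusted p from 0.031 to 0.998. MHC class I presentation had a median of 0.14 over 10 genes, with psme1 at 0.51, tap2a at 0.39 and tapbp at 0.39, and of the 2 MHC class II genes cd74a was at 0.37 and ctsh at -0.20. The 14 phagosome and lysosome genes had a median of -0.12, with the proton pump subunit atp6v1ab higher adjusted over the list alone (2.60), another subunit, atp6v0d1, at -1.10 and npc1 at 1.93. The change of npc1 ran from 1.08 to 2.47 over the alternatives. Of 21 vesicle transport genes (median -0.23), exoc7 was at -1.12 and rab8a at -0.81, and rab1a, not well above background on any control array, had a log2 change of 1.23 (adjusted p = 0.107), a bound of at least 1.82-fold higher, and of -0.63 after normexp correction.

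Among cell type markers, the 8 B cell genes had a median of -0.25, with xbp1 at -0.66, pou2af1 at -0.40 and tnfrsf13b at -0.29. The 13 T cell and NK-like genes had a median of 0.13, with eomes at 1.04, lck at 0.66 and CD4 at 0.59, each higher on every MPLE array than on every control array. Neutrophil genes had a median of 0.16 over 10 genes, with csf3r at 1.14, the myeloperoxidase mpx at -0.92 and ncf4 at 0.49. Monocyte and macrophage genes had a median of 0.38 over 11 genes, with lgmn at 1.12, apoeb at 0.95 and aif1 at 0.66. Erythroid genes had a median of 0.11 over 17 genes, with slc4a1b at 2.22, well above background on 1 of the 3 control arrays. The change of slc4a1b ran from 0.12 to 3.08 over the alternatives. The adult globins hbb (1.46) and hba (1.27), a list of 2 with values from 2 MPLE pools, were both higher adjusted over that list alone. Both are also among the 17 erythroid genes, and adjusted over those neither passed (limma adjusted p = 0.0836 for each). The 4 thrombocyte genes had a median of -0.40, with itga2b at -0.97, fli1 at -0.47 and gp9 at -0.33. The 6 progenitor genes had a median of 0.12, with cebpa at -0.57, gfi1b at 0.50 and lmo2 at 0.23. The 5 interrenal steroidogenesis genes had a median of 0.05, with star at 0.34, fdxr at 0.27 and mrap at -0.13, and the 1 chromaffin gene tested, pnmt, was at -0.03. The 8 endothelial genes had a median of -0.11, with lyve1b higher adjusted over the list alone (2.18), kdr at -1.13 and pecam1a at 0.63.

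Among metabolic lists, cholesterol synthesis had a median of 0.17 over 11 genes, with srebf2 at 0.83, hsd17b7 at 0.69 and sc5d at -0.40. The probe of srebf2 was well above background on 2 of the 3 control arrays, and its change was -0.36 after normexp correction. Fatty acid synthesis and storage had a median of 0.01 over 9 genes, with srebf1 at -0.60, fabp4 at 0.50 and thrsp at -1.48. The level of thrsp was -4.89 in MPLE pool 1 against -0.51 and -1.40 in the other MPLE pools. Its change ran from -2.36 to -0.17 over the alternatives. Fatty acid oxidation had a median of -0.20 over 15 genes, with acsl1a at -0.90, acaa2 at -0.83 and cpt1ab at 0.73. Glycolysis had a median of -0.20 over 14 genes, with muscle phosphofructokinase, pfkmb, lower adjusted over the list alone (-2.26), ldha at -1.38 and gapdhs at 1.82. The 28 oxidative phosphorylation genes had a median of -0.06, and 0.33 after normexp correction (adjusted p = 0.00202), with atp5a1 at 1.87, cox8a at 1.03 and ndufb9 at 0.91. The 8 xenobiotic metabolism genes had a median of -0.06, with cyp1a at 1.25, aldh3a2 at 0.40 and porb at -0.72. The 7 growth and IGF axis genes had a median of -0.17, with pik3ca at 0.91, pik3r1 at 0.68 and ghrb at -0.49.

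Among stress and growth functions, the 21 antioxidant genes had a median of 0.02, with gss at 1.28, gstt1a at 0.89 and tkt at -1.02. Over the alternatives gss ran from 0.62 to 2.43. Heat shock and unfolded protein genes had a median of -0.07 over 16 genes, with the chaperone hspa8 higher adjusted over the list alone (1.42), canx at 0.64 and manf at 0.62. The 7 glucocorticoid response genes had a median of -0.05, with pck1 at -2.61, cebpb at 0.70 and fkbp5 at -0.73. The 29 cell cycle genes had a median of -0.38, as had the 27 in the set test (adjusted p = 0.408), with birc5b at 1.64, ccne1 at 1.18 and pola1 at -1.13. Translation factors and ribosome biogenesis genes had a median of 0.06 over 21 genes, with eef1a1a at 0.86, eif3a at 0.76 and bop1 at 0.72. The 13 proteasome and ubiquitin genes had a median of -0.26, with ube2n at -1.02, psmc5 at 0.91 and psma5 at -1.31. The 8 apoptosis genes had a median of 0.46, with casp3a at 1.00, bada at 0.91 and casp3b at 0.88. The probe of casp3b was well above background on 1 of the 3 control arrays, and after normexp correction its change was -0.45 and the apoptosis median -0.07. Extracellular matrix genes had a median of 0.19 over 11 genes, with timp2a higher (1.67) and bgnb lower (-1.76) adjusted over the list alone, and col1a1b at 1.21. The 12 immediate early genes had a median of -0.38, with klf4 at 2.35, fosl2 at 0.89 and jun at -0.87. The probe of fosl2 was well above background on 1 of the 3 control arrays, and its change was -0.43 after normexp correction.

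Markers of other tissues were also read. Of 9 kidney tubule genes (median -0.26), cdh16 (-2.05) and slc22a6l (-2.09) were lower and slc5a1 (1.14) and agxt2 (1.08) higher adjusted over the list alone. The probe of slc5a1 was well above background on 1 of the 3 control arrays and that of agxt2 on 2, and after normexp correction their changes were -0.39 and 0.28. The 9 hepatocyte genes had a median of -0.92, and the 8 in the set test of -0.96 (adjusted p = 0.762), with apoa2 at -2.39, hpxa at -1.94 and hamp at 0.67. The 6 adipose genes had a median of 0.34, with cidea (1.08) and cfd (2.22) higher adjusted over the list alone and cidec at -0.83. Of 3 exocrine pancreas genes, prss1 was higher adjusted over the list alone (1.53), cpb1 was at -0.07 and ctrl at 0.01, and the 1 thyroid gene, dio1, was at 0.34.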

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

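The comparisons with spike-in probes and with random lists matched on brightness for the ribosomal genes were chosen after those results had been seen, as was the check of slides against diet. The test without control pool 3, the second muscle list and the splits of the arrays were written down before their results were seen. After the first results were seen, the reading of 3 tests was tightened so that a difference has to exceed its bootstrap interval; before that, the tests of bright probes, of the second muscle list and of the muscle list without control pool 3 had counted against their explanations. For the last of these the bootstrap interval left the question open, and the genes were then tested singly, which was also chosen after the result was seen.

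A signal outside the comparisons of fish transcripts drew attention, that of the spike-in RNA. Probe E1A_r60_3 was 2.91 higher on the log2 scale on MPLE arrays than on control arrays, and E1A_r60_n9 was 2.15 higher, beyond the spread between pools of either diet. The first of these is measured against a signal near background, since 1 to 9 of its 32 spots on a control array were well above background, and the bound is at least 2.42.

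The first pattern is that more probes were called higher (97) than lower (11) with MPLE. The excess of higher calls stayed without the weak array of control pool 3, where 84.3% of the 140 probes called were higher (95% Wilson interval 77.4 to 89.4). That array is thus not needed for the excess under this scaling. The interval treats probes of the same arrays as independent and does not measure the spread between pools. That the filter let in probes dim on control arrays was tested too and, after its result was seen, not kept as an explanation of its own: of 112 probes called among those well above background on all arrays 90 were higher, but at unadjusted p the split there was 1472 to 1443, so for the wider set it stays open. A technical difference between the slides that carried the 2 diets remains a candidate explanation, since a spike-in probe with all spots well above background differed by 2.15, within the range of the called changes (1.71 to 5.65), although another batch of spike-in RNA could give that difference without moving fish transcripts. An effect of the diet stays open and cannot be told apart from it, because 0 slides carried both diets.

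The second pattern is the rise of ribosomal protein genes. Their median of 0.72 lay above 99.6% of 10000 random lists matched on brightness, whose central 95% ran from 0.11 to 0.58. These lists were drawn from all named genes, the ribosomal ones included, so that range holds part of the rise it was set against. The bootstrap interval of the median (0.56 to 1.12), which treats genes as independent, reaches into that range. The comparison cannot decide whether a shift shared by all bright probes accounts for part or all of the rise. A technical difference between the slides that carried the 2 diets also remains a candidate explanation: of the 3 spike-in probes at least as bright as the list's lower quartile, 1 was higher by more than the list's median, at 2.15. Of the other control probes as bright, DCP_1_4 (1.04) and DCP_1_7 (1.00) also exceeded that median, while DCP_1_0 (0.37), DCP_1_1 (0.14) and DCP_1_2 (0.10) did not. The slope of the spike-in dilution line was 0.81 to 0.889 on control arrays and 1.05 to 1.06 on MPLE arrays. The diet stays open here too, with 0 slides that carried both diets.

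The third pattern is the fall of skeletal muscle genes. If more muscle tissue in the control pools were the source, other muscle genes should be lower as well. A second list written before its values were read had 10 genes tested, a median of -0.28 and 7 genes below 0, at the 7.89th percentile of random lists matched on brightness, and with a bootstrap interval of -0.81 to 0.79 it decides nothing, while without control pool 3 its median was 0.08 over 12 genes, 5 of them below 0, at the 56.2th percentile; its brightest gene, eno3, also on the glycolysis list, was at 2.01, 1.91 and 3.05 in the control pools and 1.91, 1.99 and 2.13 in the MPLE pools, and fbp2 was at -1.36, -1.69 and -1.69 against -3.57, -3.25 and -2.04. Without control pool 3 the median of the first list was -1.38 (bootstrap interval -1.94 to 0.08), below all matched random lists drawn. That interval leaves open whether control pool 3 accounts for the list as a whole. Of its 8 genes, casq1b, actn3b, ckmb and TNNT3 were then lower adjusted over the list alone, while tpm2 was at 0.08 and casq1 at 0.59. Control pool 3 alone thus does not account for these 4 genes. With an estimated correlation of 0.59 in the list, they are not 4 separate observations. The diet cannot be told apart from differing tissue or slides, since 0 slides carried both diets and each pool belongs to 1 diet.

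The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 108 probes and 47 genes past the adjusted threshold and the highest of the others 0 and 0, so that 1 split of 10 gave as many. At unadjusted p it gave 4024 probes, the highest of the others 1574, and again 1 split of 10 gave as many. For gene lists the real split gave 2 and the highest of the others 2, with 5 splits of 10 giving as many.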

How the results depend on the processing

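The counts of calls depended on the processing, and the cause was not tested except where stated. Of probes past the adjusted threshold (108), 19 were left by quantile normalization, 17 of them among the 108, 9 in the deposited series values, 0 by limma without the filter on dim probes (4107 at unadjusted p), where 42384 probes were tested, 630 passed with array weights, 638 at a threshold of 0.1, and, chosen after seeing the data, 28 after normexp and 14 with spike-in centring. For genes (47) these were 11, 1, 0 and 348, then 8 and 6, and 1 when adjusted over 1 probe per gene. At unadjusted p (4024), spike-in centring gave 8242 probes. For gene lists (2), an estimated correlation and fry each left 0 and spike-in centring 1, as the muscle list, at -1.93, had an adjusted p = 0.149. Leaving out 1 array gave 0 to 164 probes, 0 to 83 genes, 2095 to 5236 probes at unadjusted p and 2 to 3 lists. With the pool number as a block, 475 probes, 225 genes and 4 lists passed; the numbers share only a name, since deviations of same-numbered pools correlated at -0.18, -0.34 and 0.083 and 0 of 6 arrays came closest to its own number. Complement and acute phase genes passed as a list with that pool block (-0.79, adjusted p = 0.031) and without control pool 1 (-2.17, adjusted p = 0.0389), against 0.762 in the chosen setting, and hepatocyte genes with the block (-0.96, adjusted p = 0.0188). The oxidative phosphorylation list turned from -0.06 to 0.33 after normexp (adjusted p = 0.00202, and 0.617 to 0.998 under the others). Both called lists kept their direction under all 20 alternatives run on them, with medians of 0.30 to 0.89 for ribosomal proteins and -1.93 to -1.04 for muscle. The named genes past the threshold kept their sign under all alternatives run and lost the call without the dim-probe filter, adjusted over 1 probe per gene, in the deposited values (where catip had none), without control pool 1 and without each MPLE pool. Of those the text names, phf1, catip and sema6bb passed with quantile normalization, blzf1 after normexp, and agxtb, sema6bb and rell2 with spike-in centring. Of 149 named genes 25, and of 37 lists 28, turned sign under some alternative other than those that only recentre the arrays, and 8 and 1 more only by recentring, which was counted apart after these results were seen and where spike-in centring moved probes with a value on every array by -0.44; 0 of either were past the threshold in the chosen setting. The median change of all probes, -0.01, moved to -0.24 without the filter, -0.13 with probes well above background on all arrays, 0.22 in the deposited values, -0.21 after normexp and -0.46 with spike-in centring. Only spots well above background carry a measured level, 42.5% of them in control pool 3 against 77.8% in MPLE pool 2. Slide as a block, normexp on mean signals and matching by symbol alone, all planned, were not run as alternatives of their own.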

Other observations

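For the liver transcripts apoa2, fgg and hpxa, the range between the pools of either diet was wider than the difference between the means of the diets, and none passed the adjusted threshold. The apolipoprotein apoa2 was at 0.94, 4.20 and 2.06 in the control pools and -2.86, 2.00 and 0.89 in the MPLE pools. The fibrinogen chain fgg was at -3.02, 0.65 and -1.70 in the control pools and -5.65, -1.04 and -2.13 in the MPLE pools. In both, control pool 2 was highest and MPLE pool 1 lowest. The haemopexin hpxa was at -2.25, 0.54 and 0.56 in the control pools and -4.25, -0.86 and -1.88 in the MPLE pools.

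The transcription factor klf4 was at 1.36 and 1.07 in control pools 1 and 2, at -2.75 in control pool 3 and between 2.16 and 2.40 in the MPLE pools. The muscle tropomyosin tpm2 stood at 3.78 in control pool 3 and between -0.14 and 0.48 in the other 5 pools. The slope of the spike-in dilution line that Feature Extraction writes was 0.889, 0.862 and 0.81 on control arrays and 1.05, 1.05 and 1.06 on MPLE arrays.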
